A study of Mus musculus with 12 samples.

How the data were processed

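Bulk RNA sequencing of mouse forelimb buds gave 12 libraries in 4 groups of 3. According to the labels, each replicate is 1 pair of forelimb buds from a Swiss albino embryo, flash frozen before RNA extraction with an RNeasy kit. The labels state an RNA integrity number of at least 8.0, libraries made with a SMARTer kit and single-end reads of 85 bp on a NextSeq 500. The strand protocol, the litters and the days of dissection and sequencing are not given in the sources used here.

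The authors' processing notes name FastQC 0.11.4, STAR 2.5.2 and RSEM 1.3.0 on mm10. The deposited values are RSEM expected counts (unit expected_counts), 1 value per Ensembl gene and library, not normalised. Of all values, those of 0 included, between 12.5% and 16.2% per library were not whole numbers, which is usual for RSEM values, and all values were rounded before testing. The files hold 53465 genes, of which 53274 have a symbol in the annotation used here (GENCODE M21, GRCm38) and 191 have none. Genes were matched by Ensembl identifier. An expected count sums the reads of all exons of a gene, so a gene that is transcribed but cannot make its protein can keep its count. Because the strand is not stated, overlapping genes on opposite strands, such as Hand2 and Hand2os1, are hard to tell apart.

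Total counts ran from 23.3 to 31.8 M (1e6) counts in the 6 libraries of the Tbx3 series and from 60.2 to 68.6 M in the 6 libraries of the Hand2 series. Replicates varied far beyond counting error, which alone gives a chi-square per gene of about 1. Over 12 pairs of replicates it was 14.04 to 223.4, among genes with at least 20 counts summed over the pair. The highest values, 209.23 and 223.4, were those of Hand2-deficient replicate 1, which had 5.37% of its counts on 1 ribosomal-RNA-like gene. Pairs without that library reached at most 29.62. The errors given are therefore those between replicates, and reads without molecular identifiers are not independent molecules.

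Each mutant group was compared with its own wild-type group in a fit of 6 libraries, with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (minimum count 10, minimum total 15), the quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and an adjusted p given without another name is from this test. Log2 fold changes are deficient over wild type with edgeR's prior count of 0.125, and their standard error (SE) is the fold change divided by the square root of F. CPM are counts scaled by TMM to 1e6 per library, given as mean and SD of 3 libraries. The difference between both effects (Hand2 effect minus Tbx3 effect) was tested in a 4-group fit of all 12 libraries. Stage, colony, the gene targeted and the kind of loss (a Tbx3 allele on both copies, Hand2 lost in the limb mesenchyme) differ together between both series. A difference of effects cannot be assigned to any of them. Depth differs as well, and was examined by thinning the Hand2 counts to the Tbx3 depth.

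Genes called in both comparisons were counted among those tested in both, with Fisher's exact test, 1-sided, in each direction. Genes are not independent replicates in such a test. The choice of the groups, tests, alternatives, the rule for named genes and 33 gene lists (395 entries, 373 distinct genes) was made before the data were examined. The lists cover limb patterning (anterior, posterior, SHH response, SHH co-receptor, 5′ Hox, apical ridge and ectoderm, proximal and early mesenchyme genes) and pathways (FGF, BMP, WNT, retinoic acid and NOTCH). Others cover cell states (chondrogenic, extracellular matrix, proliferation, p53 and cell death, TBX3-repressed, hypoxia and glycolysis, immediate early, ribosomal protein and sex-linked genes). Markers of other cells that a bud sample could hold make up the rest (red cell, endothelial, macrophage, epithelial, muscle progenitor, neural crest, neuron, somite, body wall, cardiac and hindlimb). They were tested with camera in limma 3.58.1 on logCPM (prior count 2) with its preset correlation of 0.01, adjusted over the lists of a comparison. Each list also has a camera test with an estimated correlation and a fry test. Fry tests whether the genes of a list move one way on balance, not whether they move more than other genes.

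Named genes are both targeted genes, the 10 largest rises and 10 largest falls among called genes with a curated symbol, a mean of at least 5 CPM in the higher group and no overlap between groups, list members, and genes called in both comparisons. All members of the anterior, posterior, SHH response and SHH co-receptor lists are named, and up to 4 called members of each other list. Of genes called in both comparisons, 10 per direction and all opposite ones are named, as are the 6 with the smallest adjusted p for the difference. Some genes that this rule names are not reported here, and counts over lists and over named genes that lost or gained a call include them. Outside this rule, Slc2a1, Hk2, Ankrd37, Aldh1a2 and Tbx4 in the Tbx3 comparison and Dlx2, Lhx2, Gata6 and Tbx4 in the Hand2 comparison were chosen after their values were seen.

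On simulated data with the depth and spread of these libraries, edgeR found 64% of planted 1.5-fold changes in the Tbx3 comparison and 72% in the Hand2 comparison, and 96% of 2-fold changes in both. False calls were 12 of 192 and 10 of 194. A list planted at 1.5-fold was called in both, with 0 of the other 31 and 32 lists called by camera. Simulated genes were drawn independently, so this cannot show how often camera calls lists falsely when genes are correlated. With the real libraries regrouped, camera called up to 11 lists in the Tbx3 and 10 in the Hand2 series. Alternatives were other scalings (RLE, upper quartile), other filters, DESeq2 1.42.0, limma-voom, robust dispersions, a block for the replicate number, a covariate for embryo sex from Xist and Y-linked genes, all 12 libraries in 1 fit, a 1.5-fold minimum and leaving out each library. No library was left out of the comparisons.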

Results

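Forelimb bud RNA was measured in 12 libraries, 3 in each of 4 groups. The Tbx3 series holds wild-type buds and buds labelled Tbx3-deficient at E9.75 to E10 (28 to 31 somites). In the allele named by the labels, both copies of Tbx3 carry a Venus reporter and a transcription stop at the start codon. The Hand2 series holds Prrx1-Cre wild-type buds and buds lacking Hand2 in the limb mesenchyme at E10 to E10.25 (31 to 33 somites). Total counts were 23.5, 23.3 and 25.8 M (1e6) in the Tbx3 wild-type libraries, and 24.2, 31.8 and 27.4 M in those labelled Tbx3-deficient. They were 64.4, 68.6 and 67.2 M in the Hand2 wild-type libraries and 60.2, 64.1 and 65.7 M in the Hand2-deficient ones. The first principal component separated the genotypes in both series, with 33.1% of the variance in the Tbx3 series and 44.3% in the Hand2 series.

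Hand2 (ENSMUSG00000038193, GRCm38 chromosome 8, 57320983 to 57324633), a bHLH transcription factor of the posterior limb mesenchyme, was almost lost from the Hand2-deficient buds. Its level fell from 122 ± 3.34 to 0.926 ± 1.12 CPM (mean ± SD, n = 3), 129-fold, with a log2 fold change of -7.01 (SE 0.553) and adjusted p = 0.00164 in edgeR's quasi-likelihood test. The 3 deficient libraries had 0.187, 2.21 and 0.384 CPM. Without deficient replicate 2 the log2 fold change was -8.70. Tbx3 (ENSMUSG00000018604, chromosome 5, 119670669 to 119684724), a T-box repressor, did not differ between wild-type buds and buds labelled Tbx3-deficient, at 78.2 ± 1.01 and 77.7 ± 3.92 CPM. Per library the wild types had 78.0, 77.3 and 79.3 CPM and the others 80.6, 79.3 and 73.3 CPM, for a log2 fold change of -0.01 (SE 0.0515, adjusted p = 0.954). Deficient replicate 3 alone lay below all 3 wild types. A transcription stop at the start codon would lower this count only if transcription does not run past it. Gene counts alone do not settle whether the allele was present, and these libraries are called Tbx3-deficient by label. Neither factor's gene passed the test in the other comparison. Hand2 was at 108 CPM in wild-type buds and 77.9 CPM in buds labelled Tbx3-deficient (log2 fold change -0.46, adjusted p = 0.153, lower in 3 of 3 libraries). Tbx3 was at 84.0 CPM in the Hand2 wild types and 71.2 CPM in the Hand2-deficient buds (log2 fold change -0.24, adjusted p = 0.175).

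**Figure D1:**
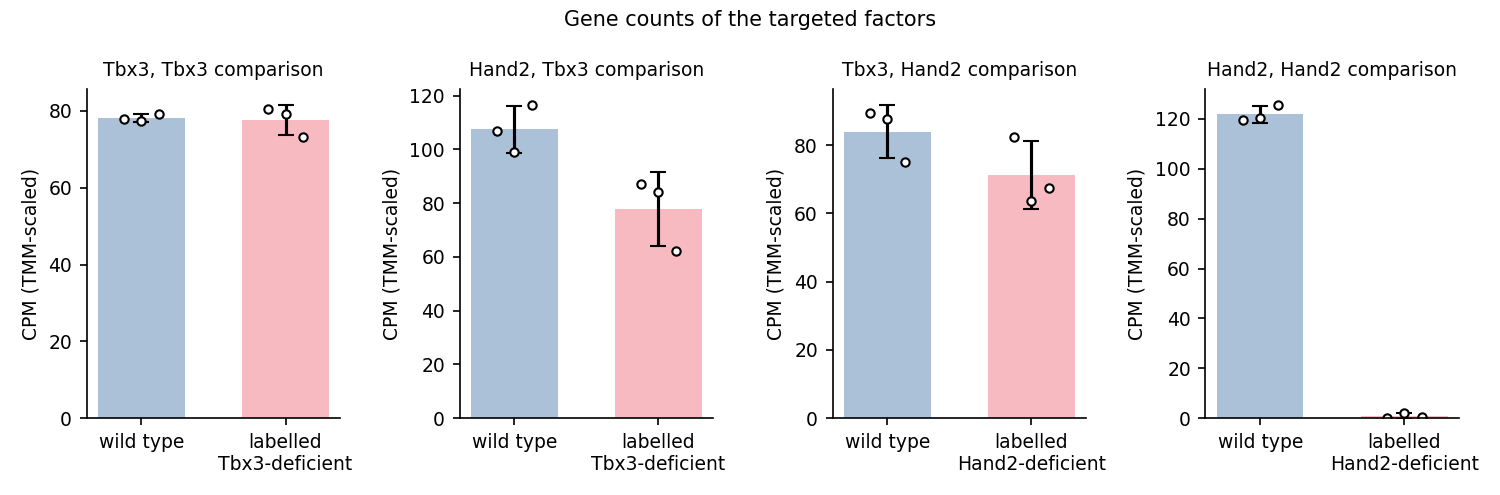
Gene counts of Tbx3 and Hand2 in each comparison, in TMM-scaled CPM (vertical axes from 0), with bars for the mean of 3 libraries, error bars for the SD and a circle per library. Hand2 fell from 122 to 0.926 CPM in the Hand2 comparison, and Tbx3 stood at 78.2 and 77.7 CPM in the Tbx3 comparison.

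The Tbx3 comparison asks which forelimb genes change when TBX3 is disrupted. In buds labelled Tbx3-deficient, genes of the low-oxygen response and glycolysis rose together, 11 of 13 measured members passing the test, with a median log2 fold change of 0.87. With embryo sex as a covariate none of them passed (adjusted p from 0.0712 to 0.249). Camera did not call their list with an estimated correlation (adjusted p = 0.314). Pitx1, a homeobox gene that normally marks the hindlimb, rose from 0.61 ± 0.25 to 12.7 ± 0.526 CPM (n = 3). The anterior gene Alx4 rose from 91.2 to 146 CPM, and the Hedgehog receptor gene Ptch1 fell from 98.7 to 68.4 CPM, calls that ended without single libraries. Camera called the retinoic acid pathway list higher and the posterior, SHH response and 5′ Hox lists lower, with 0 of 13, 1 of 13, 2 of 10 and 0 of 9 members called by edgeR. With an estimated correlation none of these 4 list calls held (adjusted p from 0.314 to 0.343).

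In total 153 of 15130 genes tested were called by edgeR, 110 higher and 43 lower, and 61 changed at least 2-fold. The median log2 fold change was 0.96 among those higher and -0.53 among those lower. With embryo sex as a covariate 12 genes were called, in a fit whose genotype effect rests mainly on deficient replicate 3, the only female deficient embryo. With the replicate number as a block 87 were called, with limma-voom 99, with DESeq2 551 and with no low-count filter 504. The count was 51, 23 and 40 without wild-type replicates 1, 2 and 3, and 220, 45 and 57 without deficient replicates 1, 2 and 3. A fit without 1 library also has fewer libraries to measure the spread, so a lost call does not show that this library decided it. Of the 48 named genes called, 27, 38 and 34 lost the call without wild-type replicates 1, 2 and 3, and 11, 31 and 28 without deficient replicates 1, 2 and 3. The 9 that kept it in all 6 cases were Rplp0-ps1, Pitx1, Bhlhe40, Gltp, Rplp0, Hoxc8, Dcun1d4, Olfm1 and Nap1l5. Camera called 14 of 32 lists, 10 up and 4 down, against 7 with fry and 0 with an estimated correlation (5 at an unadjusted p under 0.05).

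Hypoxia and glycolysis genes moved in 1 direction. Of 13 tested, 11 rose and 0 fell, and 13 rose when adjusted over the list alone (camera adjusted p = 2.82e-15, adjusted p = 0.314 with an estimated correlation, fry adjusted p = 0.0317). The hypoxia-induced mitophagy gene Bnip3 rose from 61.4 to 185 CPM and the pyruvate dehydrogenase kinase gene Pdk1 from 70.6 to 202 CPM (log2 fold change 1.52, SE 0.176, adjusted p = 0.0149). Adm, which encodes the vasodilator adrenomedullin, rose from 0.997 to 4.56 CPM and the glucose transporter gene Slc2a1 from 161 to 287 CPM. Vegfa rose from 45.8 to 71.1 CPM. Hk2 (log2 fold change 0.68, adjusted p = 0.099) and Ankrd37 (1.28, adjusted p = 0.06) did not pass. Ndrg1, also a list member, rose from 8.12 to 27.1 CPM. Other large rises, outside the list, were Bhlhe40 (2.96 to 16.4 CPM), Stc2 (4.60 to 21.1), the phosphofructokinase gene Pfkp (7.22 to 24.0) and Ddit4 (45.3 to 133). With the sex covariate the 13 members had adjusted p from 0.0712 to 0.249, at a median log2 fold change of 1.1. Calls ended without each library but deficient replicate 1 for Bnip3 (adjusted p from 0.052 to 0.099), Ndrg1 (0.0593 to 0.099) and Ier3 (0.0567 to 0.093). They ended without 3 wild types and deficient replicate 2 for Pfkp (0.059 to 0.093) and the list member Egln3 (0.0609 to 0.0816), and without wild-type replicates 1 and 3 and deficient replicate 2 for Pdk1 (0.0531 to 0.0717). They ended without wild-type replicates 2 and 3 for Adm (0.0565 and 0.0609) and Stc2 (0.066 and 0.0559), and without wild-type replicate 2 for Vegfa (0.0623) and Ddit4 (0.0586). Of immediate early genes, which respond to handling and stress, 1 of 12 rose (Ier3, 1.99 to 5.42 CPM) and 1 when adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.00399, adjusted p = 0.314 with an estimated correlation). Macrophage markers had a median of 1.52 over 5 genes, 0 called over all genes and 4 higher when adjusted over the list alone. Csf1r stood at 1.05 and 3.06 CPM, and the list had camera adjusted p = 0.00172 and adjusted p = 0.446 with an estimated correlation.

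**Figure D2:**
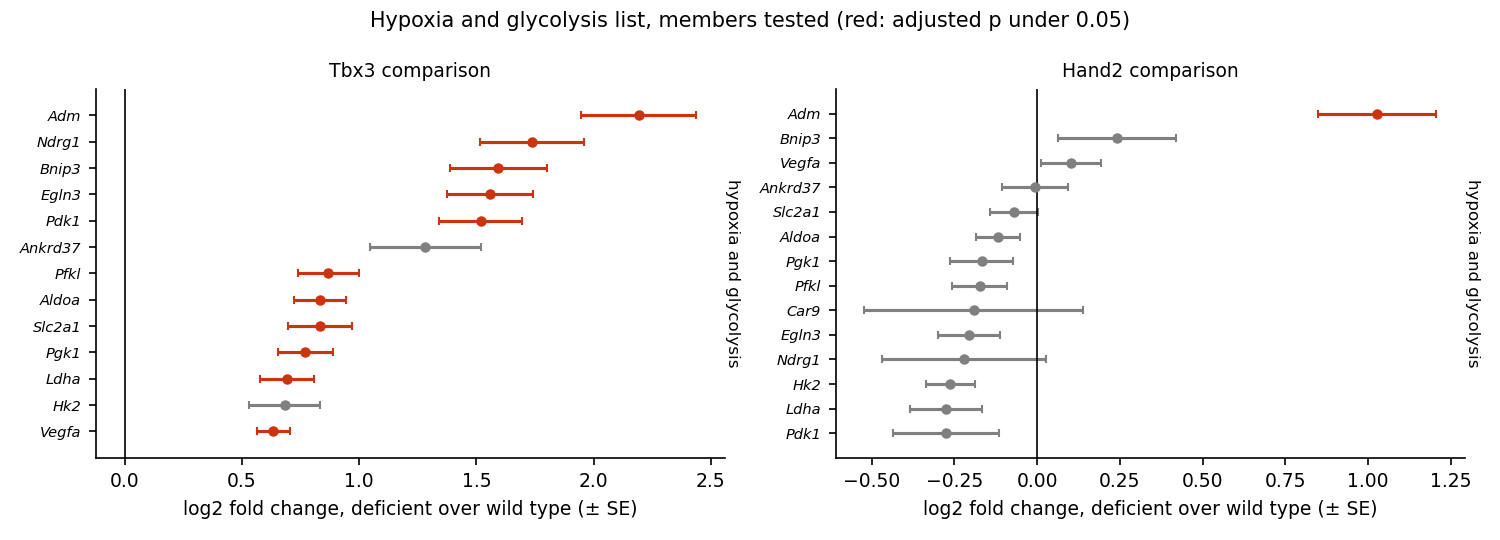
Log2 fold changes (horizontal axis, deficient over wild type) of the hypoxia and glycolysis genes tested in each comparison, with bars for the standard error and red for adjusted p under 0.05. All 13 members lie above 0 in the Tbx3 comparison, and 1 member, Adm, was called in the Hand2 comparison.

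Of 13 posterior genes tested, 1 fell, Ets2 (216 to 163 CPM), and 8 fell and 1 rose when adjusted over the list alone. The list had a median of -0.40 (camera adjusted p = 9.22e-05, adjusted p = 0.343 with an estimated correlation, fry adjusted p = 0.0989). Shh, the posterior signal, was at 5.21 and 1.78 CPM (log2 fold change -1.56, SE 0.323, adjusted p = 0.0831). Hoxd11 (81.0 and 28.1 CPM, adjusted p = 0.122), Hoxd12 (10.2 and 2.79 CPM, 0.234) and Hoxd13 (log2 fold change -0.76, 0.298) did not pass either. Further members that did not pass were Hoxd10 (log2 fold change -0.69), Sall1 (-0.29), Cyp1b1 (-0.32), Grem1 (-0.18), Bmp2 (-0.12) and the Tbx3 paralogue Tbx2 (0.62). Of 10 SHH response genes, 2 fell, Ptch1 and Prdm1 (16.8 to 7.94 CPM), which encodes a transcriptional repressor, and 2 fell when adjusted over the list alone. Their median was -0.55 (camera adjusted p = 3.78e-05, adjusted p = 0.314 with an estimated correlation). Gli1 (25.9 and 17.6 CPM) and Hhip (log2 fold change -0.59) did not pass. The posterior and SHH response lists share Hoxd12, Hoxd13, Bmp2, Grem1 and Cyp1b1, and the posterior list holds both targeted genes. Of 9 5′ Hox genes, 0 were called over all genes by edgeR and 7 fell when adjusted over the list alone, at a median of -0.69 (camera adjusted p = 3.77e-05, adjusted p = 0.343 with an estimated correlation). The Ptch1 call ended in 5 of 6 cases, with adjusted p of 0.105, 0.126 and 0.0757 without wild-type replicates 1, 2 and 3 and of 0.129 and 0.131 without deficient replicates 2 and 3. That of Ets2 ended without the same 5 libraries, at 0.102, 0.118, 0.114, 0.168 and 0.152, and that of Prdm1 without wild-type replicates 2 (0.061) and 3 (0.0559).

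Of 10 anterior genes, 1 rose, Alx4 (log2 fold change 0.68, SE 0.0816, adjusted p = 0.0153), and 4 rose when adjusted over the list alone. The homeobox genes Irx3 and Irx5 did not pass, with log2 fold changes of 0.43 and 0.44. Gli3, which opposes SHH (0.23), Alx1 (0.28), Pax1 (-0.08), Asb4 (-0.07) and Zic2 (-0.25) did not pass either. The anterior list had camera adjusted p = 0.0431, adjusted p = 0.5 with an estimated correlation, 0.0501 with the sex covariate and 0.0935 with the replicate block. Its call ended without wild-type replicate 3 (adjusted p = 0.221), deficient replicate 1 (0.195) and deficient replicate 3 (0.0749). Of 3 SHH co-receptor genes 0 were called and 2 rose when adjusted over the list alone: Boc (-0.02), Cdon (0.18) and Gas1 (0.27), camera adjusted p = 0.166. The Alx4 call ended without wild-type replicates 2 (0.0623) and 3 (0.0734) and deficient replicates 2 (0.064) and 3 (0.0507).

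**Figure D3:**
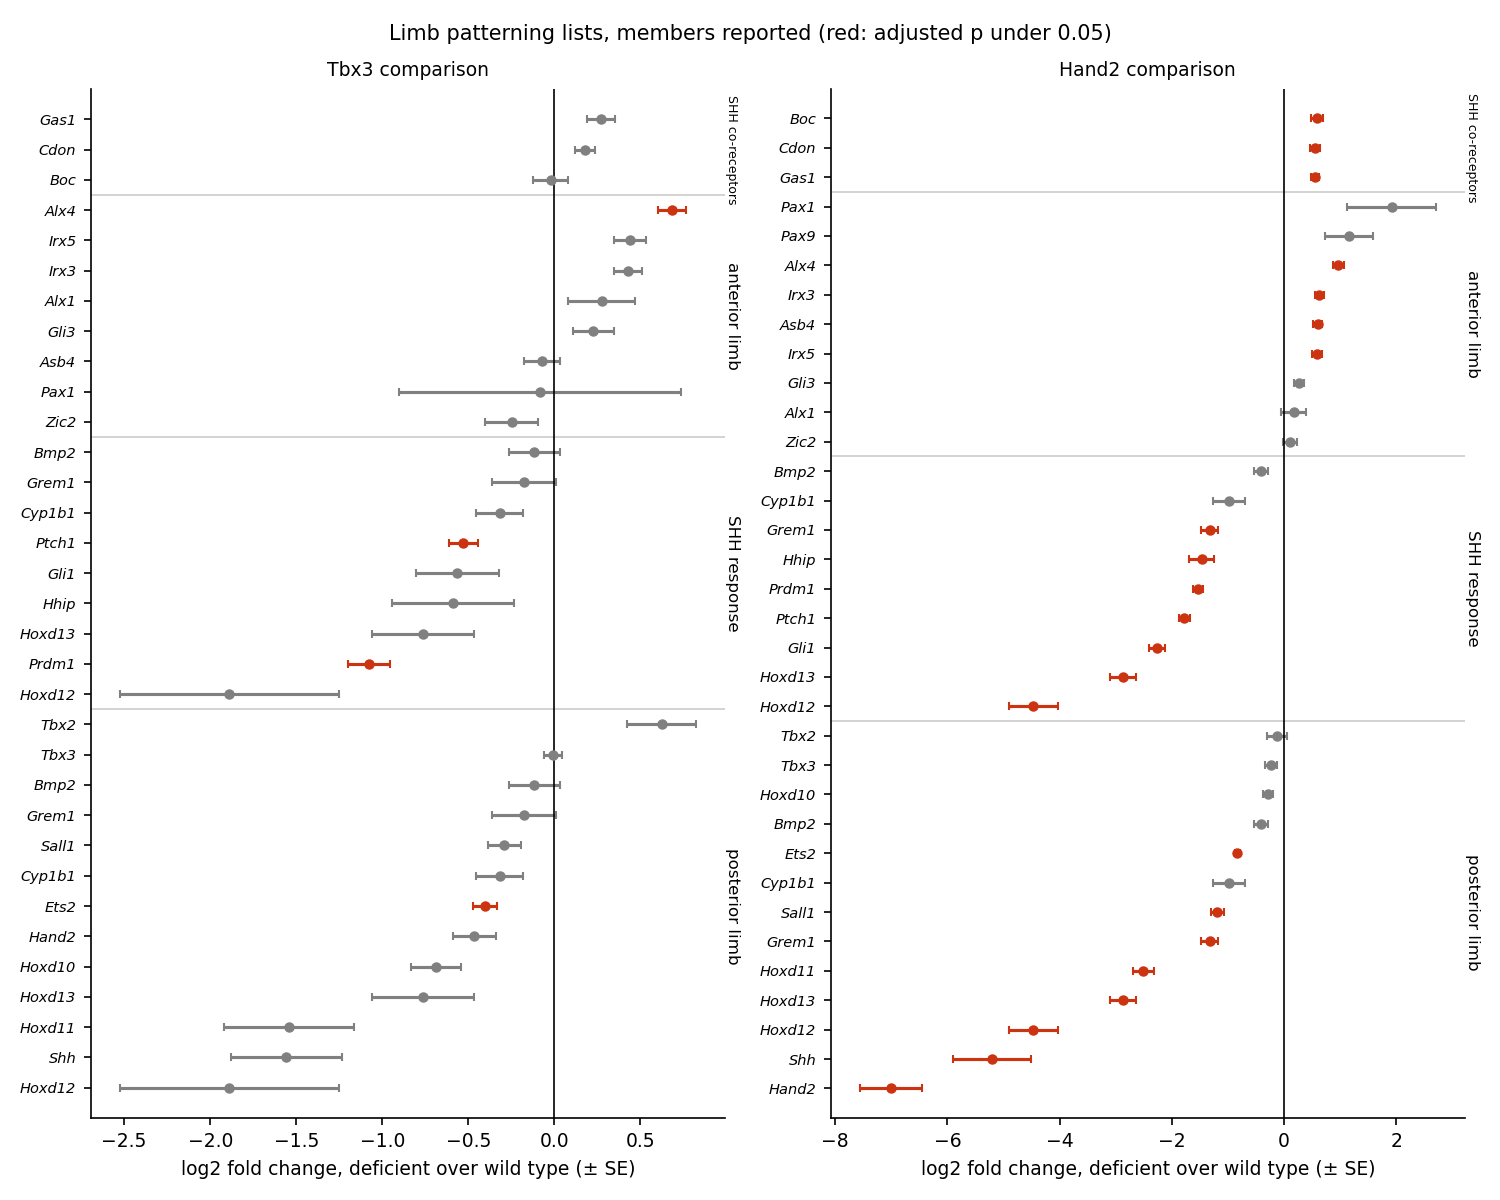
Log2 fold changes (horizontal axes, deficient over wild type, scaled apart in each panel) of the posterior, SHH response, anterior and SHH co-receptor genes reported here in both comparisons, with bars for the standard error and red for adjusted p under 0.05. Posterior and SHH response genes lie mostly left of 0 in both, down to -7.01 for Hand2, and 4 of the anterior genes shown rose in the Hand2 comparison against 1 in the Tbx3 comparison.

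Retinoic acid pathway genes had a median log2 fold change of 0.32 over 13 genes. Over all genes 0 were called by edgeR, and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.314 with an estimated correlation). Aldh1a2, which encodes the main embryonic enzyme for retinoic acid synthesis, was at 9.93 and 43.9 CPM (adjusted p = 0.13). BMP pathway genes had a median of 0.14 over 14 genes, with 0 called over all genes and 1 higher when adjusted over the list alone (camera adjusted p = 0.0146, adjusted p = 0.446 with an estimated correlation). That call ended without wild-type replicate 3 (0.102) and deficient replicate 2 (0.151) and with the sex covariate (0.105). Chondrogenic genes had a median of 0.11 over 8 genes, 0 called and 2 higher when adjusted over the list alone (camera adjusted p = 0.0455, adjusted p = 0.498 with an estimated correlation). It ended without wild-type replicates 2 (0.347) and 3 (0.0597) and deficient replicate 1 (0.188) and with the sex covariate (0.218). In the WNT list, 1 of 13 genes fell, Wnt5a, a limb outgrowth ligand (135 to 93.5 CPM), and 2 when adjusted over the list alone. In the early mesenchyme list 1 of 15 fell, Tbx5, which is required for forelimb initiation (90.2 to 62.4 CPM), and 3 when adjusted over the list alone. In the ribosomal protein list 1 of 20 fell, Rplp0, and 1 rose and 1 fell when adjusted over the list alone. Wnt5a lost its call without each library but deficient replicate 1, with adjusted p of 0.0821, 0.118 and 0.119 without wild-type replicates 1, 2 and 3 and of 0.161 and 0.155 without deficient replicates 2 and 3. Tbx5 lost it without the same libraries, at 0.105, 0.109, 0.126, 0.142 and 0.0809 in that order.

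Lists without a camera call in the Tbx3 comparison were WNT (adjusted p = 0.373), early mesenchyme (0.0764), ribosomal protein (0.238), apical ridge and ectoderm (0.54), FGF response (0.52), proximal (0.699), NOTCH (0.223), extracellular matrix (0.947), proliferation (0.654), p53 and cell death (0.325) and TBX3-repressed genes (0.54). No single gene passed in the last 8 of these over all genes tested. Adjusted over the list alone, 2 proximal genes rose and 3 fell, 1 TBX3-repressed gene rose and 1 fell, and 1 NOTCH gene and 1 extracellular matrix gene rose. For extracellular matrix genes the median (-0.04) and the mean (0.09) had opposite signs, and for WNT genes the median was 0.00 and the mean -0.06.

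Camera called some lists of markers of other cells in the Tbx3 comparison. Body wall and coelomic markers had a median log2 fold change of 1.68 over 7 genes, 0 called over all genes and 3 higher when adjusted over the list alone. Gata6 was at 11.4 and 33.4 CPM (adjusted p = 0.174) and Wt1 at 5.05 and 13.6 CPM (adjusted p = 0.386). This list had camera adjusted p = 0.00299 and adjusted p = 0.534 with an estimated correlation, 0.0626 without wild-type replicate 3 and 0.0978 with the sex covariate. Of 5 hindlimb markers tested, 2 rose, Pitx1 and Hoxc9 (5.20 to 10.6 CPM), and 2 when adjusted over the list alone. Tbx4, the hindlimb T-box gene, stood at 2.49 and 2.42 CPM (log2 fold change -0.05, adjusted p = 0.95). The hindlimb list had camera adjusted p = 0.00562 and adjusted p = 0.314 with an estimated correlation, and 0.0827 without deficient replicate 1. Neural crest markers had a median of 0.38 over 4 genes, 0 called, 1 higher when adjusted over the list alone, Ngfr at 37.3 and 61.7 CPM and Erbb3 with a log2 fold change of 0.25 (camera adjusted p = 0.0455, adjusted p = 0.343 with an estimated correlation). Their call ended without wild-type replicates 1 (0.198) and 2 (0.067) and deficient replicates 1 (0.0827) and 3 (0.0716), and with the sex covariate (0.128). Red cell markers were lower as a list, at a median of -0.34 over 12 genes with 0 called and 0 when adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.744 with an estimated correlation). The embryonic globin gene Hbb-y stood at 1267 and 961 CPM and Hba-x had a log2 fold change of -0.30. That call ended without wild-type replicate 1 (0.268) and deficient replicates 1 (0.341) and 2 (0.271), and with the sex covariate the list was higher (adjusted p = 0.0114). Somite markers (median 0.60, camera adjusted p = 0.0664; Meox1 at 20.4 and 35.4 CPM, Tcf15 0.40), endothelial markers (0.07, 0.654; Kdr 0.07 and Cdh5 -0.06), muscle progenitor markers (0.01, 0.54; Met 0.14 and Lbx1 -0.14), neuron markers (-0.22, 0.726; Tubb3 -0.50 and Dcx -0.44) and cardiac markers (0.12, 0.489; Actc1 0.12 and Tnni1 0.87) were not called. Adjusted over the list alone, 4 somite markers rose and 1 fell, 1 endothelial marker rose and 1 fell, and 1 muscle marker rose. In the epithelial list 1 of 14 rose, Cldn6 (33.0 to 44.4 CPM), and 2 when adjusted over the list alone (camera adjusted p = 0.54). The call of Cldn6 ended without each library (0.0557 to 0.158), and that of Hoxc9 without wild-type and deficient replicates 2 and 3 (0.0532 to 0.064).

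Rplp0-ps1, a processed copy of the ribosomal protein gene Rplp0, rose from 0.0559 to 28.6 CPM (log2 fold change 8.90, SE 0.213, adjusted p = 9.34e-07). Rplp0 itself (chromosome 5, 115559467 to 115563727), 4.11 Mb from Tbx3, fell from 2328 ± 28.3 to 1580 ± 106 CPM. Summed with 3 of its copies, Rplp0 was at 2435 and 2645 CPM. Of their 31-base words these copies share 62.8% (Gm8730), 46.5% (Gm9625) and 23.3% (Rplp0-ps1) with Rplp0. Within 20 Mb of Tbx3, 15 of 428 genes tested were called, against 138 of 14702 elsewhere (odds ratio 3.83, 95% interval 2.07 to 6.62, Fisher's exact test, 2-sided, p = 2.93e-05). They included Tbx5, 0.162 Mb from Tbx3, Sparcl1, which encodes a matricellular protein (6.94 to 19.9 CPM), and the glycolipid transfer protein gene Gltp (29.2 to 18.1 CPM). Among called genes with a curated symbol (gene models with Gm names left out), at least 5 CPM in the higher group and no overlap between the groups, the largest falls were those of the collagen VI gene Col6a3 (10.2 to 3.67 CPM, log2 fold change -1.47), Prdm1 (-1.08) and the receptor gene Egfr (8.83 to 4.48 CPM). Sel1l3 (-0.91), the integrin gene Itga4 (-0.86), the WNT antagonist gene Wif1 (-0.83), the mitochondrial ribosomal RNA mt-Rnr2 (-0.77), Kank4 (-0.72), the protocadherin gene Pcdh17 (-0.72) and Gltp (-0.69) followed. All 10 were lower in 3 of 3 libraries, which the rule of no overlap requires. Col6a3, Egfr, Sel1l3, Itga4, Wif1, mt-Rnr2, Kank4 and Pcdh17 are among the 39 named genes that lost the call without at least 1 library. Egfr, Sel1l3 and Pcdh17 lost it without each library (adjusted p from 0.0557 to 0.166), and the other 5 without wild-type replicate 2 (0.0902 to 0.124) among others. Sparcl1 lost it without wild-type replicate 2 (0.052).

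**Figure D4:**
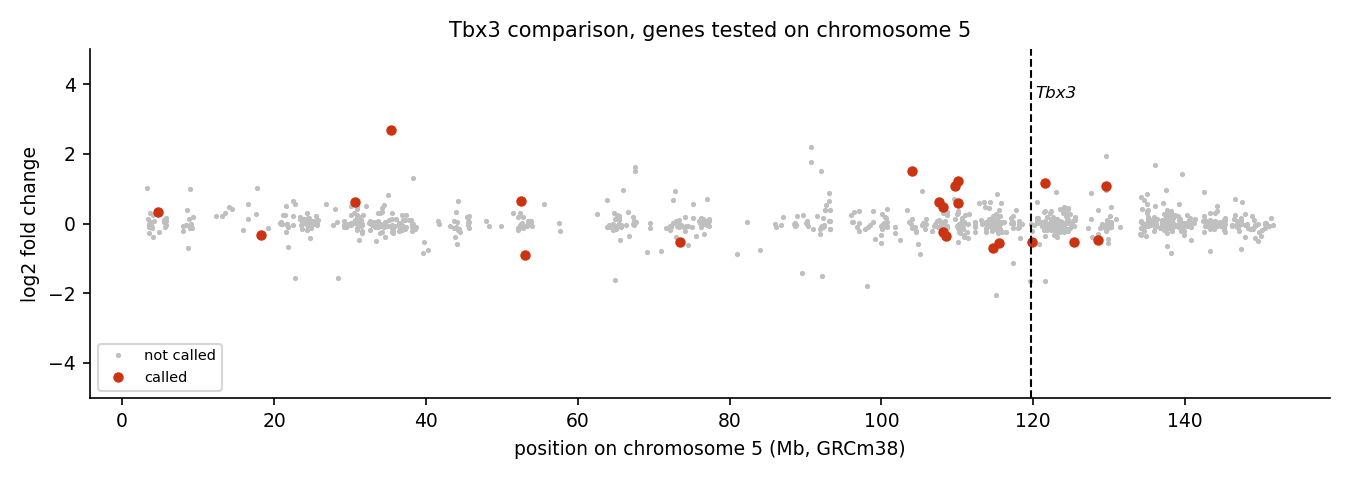
Log2 fold change (vertical axis, labelled Tbx3-deficient over wild type) of each gene tested on chromosome 5 against its position in Mb of GRCm38, with called genes in red and Tbx3 as a dashed line. Within 20 Mb of Tbx3, 15 of 428 genes were called.

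The Hand2 comparison asks which forelimb genes change without HAND2 in the mesenchyme. Shh fell from 7.28 to 0.193 CPM (log2 fold change -5.20, SE 0.691, adjusted p = 0.0108), and the genes that respond to SHH fell with it, 8 of 10 passing the test at a median log2 fold change of -1.65. The 5′ Hoxd genes Hoxd11, Hoxd12 and Hoxd13 fell, to 15.8, 0.917 and 7.81 CPM from 89.8, 20.4 and 56.9 CPM. Of 11 anterior genes 5 rose, among them Alx4 from 92.9 to 182 CPM. All 3 genes of SHH co-receptors rose, and the ridge signals Fgf4 and Fgf8 were called lower, calls that ended without single libraries.

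In total 1836 of 17488 genes tested were called by edgeR, 818 higher and 1018 lower, and 317 changed at least 2-fold. The balance of directions depended on the scaling, with 1047 higher and 504 lower under upper quartile scaling. Most called changes were small, with a median log2 fold change of 0.59 among those higher and -0.26 among those lower, and 588 reached 1.5-fold. The count was 3475 with DESeq2, 550 with the sex covariate, 161 with the replicate number as a block and 1209 with the counts thinned to the depth of the Tbx3 series. It was 368, 2223 and 218 without wild-type replicates 1, 2 and 3, and 487, 1054 and 366 without deficient replicates 1, 2 and 3. Of the 97 named genes called, 42, 13 and 65 lost the call without wild-type replicates 1, 2 and 3, and 46, 33 and 57 without deficient replicates 1, 2 and 3. Those that kept it in all 6 cases were 31, among them Shh, Hoxd11, Hoxd12, Hoxd13, Ptch1, Gli1, Prdm1, Grem1, Ets2, Sall1, Alx4, Asb4, Spry4, Meis1 and Snai1. Camera called 18 of 33 lists, 11 up and 7 down, against 13 with fry, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 10 without deficient replicate 2. Deficient replicate 1 had 5.37% of its counts on 1 ribosomal-RNA-like gene, against 0.13% to 0.58% in the other 11 libraries.

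Of 13 posterior genes tested, 8 fell and 0 rose, and 11 fell when adjusted over the list alone (median -1.19, camera adjusted p = 5.39e-09, adjusted p = 0.385 with an estimated correlation). Beside Hand2, Shh and the Hoxd genes, the BMP antagonist gene Grem1 fell from 55.0 to 21.9 CPM, Ets2 from 226 to 127 CPM and the zinc finger gene Sall1 by 1.19 on the log2 scale. Hoxd10 (log2 fold change -0.29, adjusted p = 0.0842), Bmp2 (-0.41, 0.0771), Cyp1b1 (-0.98, 0.0658) and Tbx2 (-0.12) did not pass. In the SHH response list 8 of 10 fell, and 10 when adjusted over the list alone (camera adjusted p = 2.53e-10, adjusted p = 0.425 with an estimated correlation). Ptch1 fell from 116 to 33.8 CPM (log2 fold change -1.78, SE 0.0957, adjusted p = 0.00032), the SHH-induced transcription factor gene Gli1 by 2.27 on the log2 scale and Prdm1 from 14.6 to 5.04 CPM. Hhip, a Hedgehog antagonist, fell by 1.47 on the log2 scale. Of 3 co-receptor genes, 3 rose and 3 when adjusted over the list alone, Boc (log2 fold change 0.59), Cdon (0.56) and Gas1 (327 to 478 CPM), with camera adjusted p = 0.0115 and adjusted p = 0.469 with an estimated correlation. Of 10 5′ Hox genes, 4 fell, the 3 Hoxd genes and Hoxa11 (94.4 to 69.5 CPM), and 6 when adjusted over the list alone (median -0.38, camera adjusted p = 0.000308, adjusted p = 0.425 with an estimated correlation). Of 11 anterior genes, 5 rose and 0 fell, and 7 rose when adjusted over the list alone (median 0.60, camera adjusted p = 0.000535, adjusted p = 0.425 with an estimated correlation). Among them were Alx4, Irx3 (105 to 162 CPM), Irx5 (log2 fold change 0.59) and Asb4 (633 to 959 CPM). Gli3 (257 and 308 CPM, adjusted p = 0.105), Alx1 (log2 fold change 0.17), Pax1 (1.92, 0.145), Pax9 (1.17) and Zic2 did not pass. Calls that ended without a single library here included Gas1 (0.0542) and Irx3 (0.0584) without wild-type replicate 3. Cdon lost it without wild-type replicate 3 (0.0611) and deficient replicate 3 (0.0527). The adjusted p rose highest without wild-type replicate 3 for Irx5 (0.0831), Boc (0.0836), Hhip (0.0604) and Hoxa11 (0.134).

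Camera called the apical ridge and ectoderm list lower, with 1 of 16 higher and 4 lower, and 1 and 7 when adjusted over the list alone (median -0.16, camera adjusted p = 0.0193, adjusted p = 0.425 with an estimated correlation, 0.0734 without deficient replicate 2). Fgf8, the main ridge signal, fell from 44.3 to 26.3 CPM (adjusted p = 0.0144, and 0.062 without wild-type replicate 3). Fgf4 fell from 2.48 to 0.464 CPM, Fgf9 from 1.63 to 0.767 CPM and Dlx2 by 0.41 on the log2 scale, while Rspo2 rose (0.35). The calls ended without wild-type replicate 3 and deficient replicates 1, 2 and 3 for Fgf4 (0.0954, 0.0865, 0.0594 and 0.0912) and Fgf9 (0.106, 0.0851, 0.0634 and 0.0709), and with the sex covariate for both (0.0627 and 0.0634). General epithelial markers were not called (0 of 14, 0 when adjusted over the list alone, median -0.02, camera adjusted p = 0.416), with Krt5 at -0.34 and Epcam at -0.23. Among FGF response genes 2 of 12 rose and 3 fell, the same when adjusted over the list alone. The feedback inhibitor genes Spry4 (-0.52) and Spred1 (-0.23) and the cyclin gene Ccnd1 (270 to 188 CPM) fell, and Lhx9 (0.54) and Lhx2 (0.46) rose. The FGF list was not called (camera adjusted p = 0.606), and its median (0.01) and mean (-0.02) had opposite signs. Camera called the WNT list lower, with 3 of 13 called and 6 when adjusted over the list alone, where 1 rose (median -0.17, camera adjusted p = 0.0405, adjusted p = 0.494 with an estimated correlation). Dkk1 (-0.48), Apcdd1 (-0.25) and Wnt5a (151 to 121 CPM) were called. The call of Wnt5a ended without each library (0.0598 to 0.139). Without deficient replicate 3 the calls of Rspo2 (0.0805), Spred1 (0.113), Lhx9 (0.0637), Dkk1 (0.0547) and Apcdd1 (0.114) ended, and without other libraries as well, with the highest adjusted p at 0.0973, 0.15, 0.0774, 0.0615 and 0.14. The WNT list lost its call without wild-type replicate 1 (0.083) and deficient replicate 2 (0.134). Camera called the BMP list higher, with 1 of 14 called, Id2 (0.47), and 1 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0405, adjusted p = 0.505 with an estimated correlation). That call ended without wild-type replicates 2 (0.136) and 3 (0.117) and deficient replicates 1 (0.126) and 3 (0.0545), and with the sex covariate (0.0771).

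Genes of the proximal limb moved both ways. Of 13 tested, 4 rose and 1 fell, and 6 and 4 when adjusted over the list alone. The homeobox gene Meis1 (79.9 to 110 CPM) and the T-box gene Tbx18 (log2 fold change 0.58) were among the rises, and the fall was that of Osr1 (14.3 to 7.18 CPM). Their median (0.17) and mean (-0.06) had opposite signs, and the list was not called (camera adjusted p = 0.286, fry adjusted p = 0.0421). Of 14 retinoic acid pathway genes 2 rose, Meis1, which the proximal list also holds, and Dhrs3 (0.57), and 2 when adjusted over the list alone (median 0.12, camera adjusted p = 0.123, fry adjusted p = 0.0421). In the early mesenchyme list 4 of 15 rose and 2 fell, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.636). Fgf10, which keeps outgrowth going, fell from 40.2 to 26.2 CPM and Snai1 by 0.50 on the log2 scale, and Prrx2 rose (0.53). NOTCH genes Jag1 (-0.43) and Hey1 (-0.39) fell, 2 of 11 and 2 when adjusted over the list alone (camera adjusted p = 0.124). Of extracellular matrix genes 4 of 19 rose, and 5 when adjusted over the list alone, with Col1a2 from 281 to 583 CPM, Col6a2 (0.62), Sparc (0.33) and Col5a1 (0.30) called (median 0.30, camera adjusted p = 0.0197, adjusted p = 0.505 with an estimated correlation). Of chondrogenic genes 1 of 9 rose, Sox5 (0.60), and 3 when adjusted over the list alone (median 0.40, camera adjusted p = 0.0277, adjusted p = 0.425 with an estimated correlation). This call ended without deficient replicates 1 (0.0506) and 3 (0.0545). Of proliferation genes 6 of 21 fell, and 9 when adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.00691, adjusted p = 0.494 with an estimated correlation). Ccne2 (-0.43), the replication helicase genes Mcm2 and Mcm3 (both -0.22) and Ccnb1 (-0.21) were called. In the p53 and cell death list Trp53inp1 rose (0.64) and Bax fell (-0.14), 1 and 1 of 14, the same when adjusted over the list alone (camera adjusted p = 0.606). TBX3-repressed genes had 0 of 6 called, and 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.675). Of 14 hypoxia and glycolysis genes 1 rose, Adm (0.511 to 1.04 CPM), and 1 when adjusted over the list alone, at a median of -0.17 (camera adjusted p = 0.261). Ribosomal protein genes had 0 of 20 called and 0 when adjusted over the list alone, at a median of -0.05 (camera adjusted p = 0.0445, adjusted p = 0.755 with an estimated correlation). Beside Meis1 and Snai1, each gene named as called in this paragraph lost the call without wild-type replicate 3 (adjusted p from 0.0767 to 0.172) and deficient replicate 3 (0.0617 to 0.14), and most without further libraries. The ribosomal list call ended without wild-type replicates 1 (0.114) and 3 (0.0541) and deficient replicates 1 (0.251) and 2 (0.0517), and with the sex covariate (0.0878).

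Of 11 macrophage markers 2 rose, the complement gene C1qb (0.439 to 1.28 CPM) and the mannose receptor gene Mrc1 (1.14 to 2.97 CPM), and 8 when adjusted over the list alone (median 1.09, camera adjusted p = 0.000578, adjusted p = 0.494 with an estimated correlation). Of endothelial markers 1 of 13 rose, Cdh5 (0.16), and 4 when adjusted over the list alone (median 0.14, camera adjusted p = 0.026, adjusted p = 0.494 with an estimated correlation, 0.105 without deficient replicate 2). Muscle progenitor markers had 0 of 10 called, 0 when adjusted over the list alone and a median of 0.32, with Met at 0.33 and Lbx1 at 0.17 (camera adjusted p = 0.0253, adjusted p = 0.494 with an estimated correlation, 0.0722 without deficient replicate 2). Of 8 body wall markers 1 rose, Gata4 (0.57 to 4.98 CPM), and 1 when adjusted over the list alone (median 1.12, camera adjusted p = 0.0437, adjusted p = 0.58 with an estimated correlation). Gata6 was at 10.6 and 18.9 CPM, and the list call ended without wild-type replicate 3 (0.0561) and deficient replicates 2 (0.176) and 3 (0.0881). Of hindlimb markers 3 of 5 rose, Pitx1 (0.961 to 2.53 CPM), Hoxc9 (3.84 to 5.99 CPM) and Isl1 (0.41 to 1.24 CPM), and 4 when adjusted over the list alone, with Tbx4 at a log2 fold change of 0.48 (adjusted p = 0.11). The list had camera adjusted p = 0.0271, adjusted p = 0.425 with an estimated correlation and 0.0517 without deficient replicate 2. Of immediate early genes 3 of 12 rose and 1 fell, the same when adjusted over the list alone (median 0.16, camera adjusted p = 0.0433, adjusted p = 0.469 with an estimated correlation). Egr1 went from 2.41 to 5.53 CPM, Klf4 (0.76) and Klf6 (0.35) also rose and Ier2 fell (-0.23), and the list call ended without wild-type replicate 1 (0.083) and deficient replicates 1 (0.103) and 2 (0.0722). Of 8 neuron markers 2 rose, Isl1 and Stmn2 (0.77), and 2 when adjusted over the list alone (camera adjusted p = 0.261). Red cell (median 0.15, camera adjusted p = 0.636; Hbb-y 0.32 and Hba-x 0.20), neural crest (0.20, 0.416; Ngfr 0.25 and Erbb3 0.14), somite (0.19, 0.636; Meox1 0.19 and Tcf15 0.20), cardiac (0.34, 0.499; Actc1 0.34 and Tnni1 -0.44) and sex-linked genes (0.68, 0.636) were not called, with 0 genes past edgeR's test in each. Beside Isl1 and Egr1, each gene named as called in this paragraph lost the call without wild-type replicate 3 (adjusted p from 0.0677 to 0.137) and deficient replicate 3 (0.0542 to 0.122), Cdh5 and Ier2 without every library. In the Tbx3 comparison 1 sex-linked gene was tested, too few for a list test.

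Some large changes lie in genes that belong to families, and sequence shared within these families was not tested. The class I gene H2-T22 rose from 0.944 to 7.21 CPM (log2 fold change 2.93, SE 0.242, adjusted p = 0.00188), the major urinary protein genes Mup10 and Mup9 by 2.06 and 1.63 on the log2 scale, the zinc finger gene Zfp991 from 2.86 to 11.6 CPM and the splicing factor gene Cwc22 from 64.1 to 209 CPM. Hand2os1, which overlaps most of Hand2 on the opposite strand, rose from 7.98 to 23.0 CPM, and without a stated strand its reads are not separated from those of Hand2. The lysyl oxidase gene Lox (3.41 to 9.49 CPM), Sned1 (11.3 to 28.5) and mt-Nd3 (78.4 to 190) also rose. Among the falls were the connexin gene Gja3 (8.54 to 2.11 CPM) and the heat shock gene Hspa1a (log2 fold change -1.73). Without wild-type replicate 3 the calls of Mup10 (0.067), Mup9 (0.0919), Zfp991, Sned1 and mt-Nd3 (each 0.0529) and Hspa1a (0.132) ended, that of Mup9 also without deficient replicate 3 (0.0662) and of Hspa1a without each library but deficient replicate 2. Of the genes called, 52 were pseudogenes, 34 of which share at least 50% of their 31-base words with a coding gene.

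The overlap of both comparisons addresses targets shared by HAND2 and TBX3, which the series title asks for. Of 15089 genes tested in both, 31 were called in both, 12 higher in both, 15 lower in both and 4 in opposite directions. Chance would give 5.05 higher and 2.78 lower (Fisher's exact test, 1-sided, p = 0.00449 and p = 3.41e-08). Among the shared falls were Ptch1 (log2 fold change -0.53 in the Tbx3 and -1.78 in the Hand2 comparison), Prdm1 (-1.08 and -1.53) and Ets2 (-0.40 and -0.83). Wnt5a (-0.53 and -0.32), Pou4f1 (-2.60 and -2.53), Olfm1 (-0.60 and -1.05) and Gap43 (-0.47 and -0.30), Nap1l5 (-1.75 and -1.0), Serinc5 (-0.37 and -0.76), Dcun1d4 (-0.54 and -0.29) and Crnkl1 (-0.28 and -0.18) fell as well. Shared rises held Alx4 (0.68 and 0.97), Pitx1 (4.38 and 1.39), Adm (2.19 and 1.03) and 3 genes of the HoxC cluster, Hoxc6 (0.53 and 0.46), Hoxc8 (1.00 and 0.71) and Hoxc9 (1.02 and 0.64). In the Hand2 comparison the call ended without each library but wild-type replicate 2 for Pitx1 (adjusted p from 0.0574 to 0.0936), without each but wild-type replicate 1 for Hoxc8 (0.0654 to 0.132), without each but wild-type replicates 1 and 2 for Hoxc9 (0.0574 to 0.111), and without wild-type replicate 3 for Hoxc6 (0.0513). It also ended there with the sex covariate for Pitx1 (0.0609), Hoxc8 (0.073) and Hoxc9 (0.0687). In the Tbx3 comparison it ended without each library but deficient replicate 1 for Hoxc6 (0.0717 to 0.112), without each but wild-type and deficient replicates 1 for Hoxc9 (0.0532 to 0.064), and with the sex covariate for Hoxc6 (0.231), Hoxc8 (0.0637) and Hoxc9 (0.114). Ncam1 (0.97 and 0.67), the axon guidance gene Slit1 (1.21 and 1.05), the chemokine receptor gene Ackr3 (0.84 and 0.49) and Mpp2 (0.69 and 0.36) also rose in both. Genes in opposite directions were Wif1 (-0.83 and 0.84), Pcdh17 (-0.72 and 0.55), Map1b (0.50 and -0.26) and Bhlhe41 (1.44 and -0.85). Of all genes named in this paragraph, Olfm1 and Dcun1d4 kept the call in all leave-one-out cases of both comparisons. In the Tbx3 comparison Pitx1, Hoxc8 and Nap1l5 kept it too, and the others lost it without wild-type replicate 3 (adjusted p from 0.0532 to 0.16), most without further libraries. In the Hand2 comparison Ptch1, Prdm1, Ets2, Pou4f1, Serinc5 and Alx4 kept it too, and the others lost it without wild-type replicate 3 (0.0513 to 0.152), most without further libraries. Pcdh17 and Map1b lost it without each library in both comparisons (up to 0.141 and 0.144 in the Tbx3 and 0.122 and 0.114 in the Hand2 comparison), and Wnt5a in the Hand2 comparison (0.0598 to 0.139). Across all genes tested in both, 59.6% had the same sign, and Pearson's r across genes was 0.193, where genes are not independent replicates. The number called in both was 0 with the sex covariate (edgeR, with 439 at an unadjusted p under 0.05 in both), 5 with the replicate number as a block, 17 with limma-voom, 186 with DESeq2, 103 with no filter and 107 in the fit of all 12 libraries. Without single libraries of the Tbx3 series it was 16, 7 and 7 (wild-type replicates 1, 2 and 3) and 34, 14 and 10 (deficient replicates 1, 2 and 3). In the Hand2 series it was 15, 34 and 11 without wild-type replicates 1, 2 and 3, and 12, 19 and 13 without deficient replicates 1, 2 and 3.

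**Figure D5:**
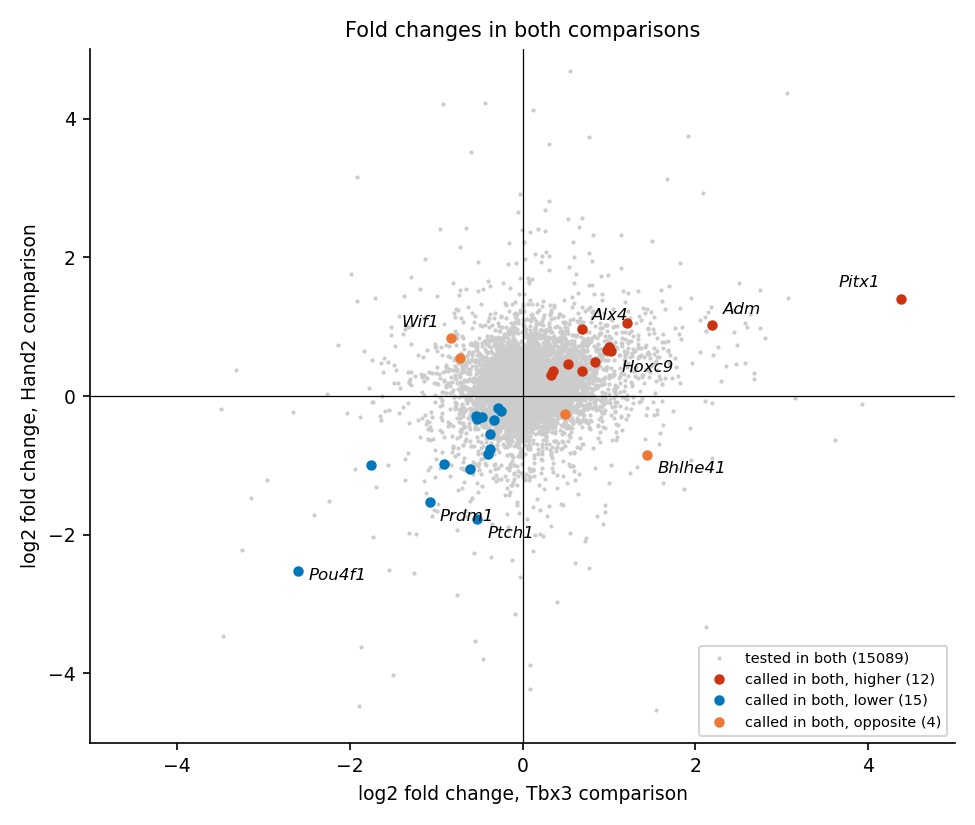
Log2 fold change in the Hand2 comparison (vertical axis) against that in the Tbx3 comparison (horizontal axis) for 15089 genes tested in both, with 15 genes outside the axes of -5 to 5 not shown. Coloured points are the 31 genes called in both, 12 higher, 15 lower and 4 in opposite directions.

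The test of the difference between both effects called 292 of 17360 genes by edgeR, 137 with a higher and 155 with a lower Hand2 effect. Of 14 hypoxia and glycolysis genes 10 differed, all with a lower Hand2 effect, among them Egln3, an oxygen sensor gene (difference of log2 fold changes -1.76, adjusted p = 0.00505), and Pdk1 (-1.79, adjusted p = 0.00994). Adm did not (-1.17, adjusted p = 0.0748). Of 10 SHH response genes 4 had a lower Hand2 effect, among them Ptch1 by a difference of -1.25 (adjusted p = 0.00235) and Gli1 by -1.70, while Prdm1 did not differ (-0.45, adjusted p = 0.147). Lists were not tested for the difference. Shh itself differed by -3.64 (adjusted p = 0.0472). The rise of Pitx1 was larger in the Tbx3 comparison, with a difference of -2.99 (adjusted p = 0.00607). The 6 smallest adjusted p belonged to Rpl34-ps1 (-1.11), Cwc22 (1.64), Rplp0-ps1 (-9.39), Hand2 (-6.55), Gltp (0.82) and Pde7b (3.72). DESeq2 called 860 genes and a block for the replicate number 69. Leaving out single libraries of the Tbx3 series gave 154, 213 and 152 genes (wild-type replicates 1, 2 and 3) and 336, 124 and 134 (deficient replicates 1, 2 and 3). In the Hand2 series it gave 123, 257 and 156 genes (wild-type replicates 1, 2 and 3) and 148, 218 and 198 (deficient replicates 1, 2 and 3).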

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

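The tests of scaling, of handling before lysis, of a mislabelled library, of DNA linked to either targeted allele, of reads shared by Rplp0 and its copies, and of hindlimb tissue were chosen only after the result was seen.

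In 41 of 146 named genes reported here the Hand2 effect and the Tbx3 effect differed by edgeR's test of the difference (adjusted p from 6.80e-05 to 0.0486). Over all genes tested it was 292 of 17360. Many named genes were chosen for their calls in these data, 6 of them by this test, so a higher share among them follows from the choice. Values are the Hand2 minus the Tbx3 log2 fold change. Members of the hypoxia and glycolysis list differed by -1.76 (Egln3), -1.79 (Pdk1) and -1.96 (Ndrg1). Limb patterning genes differed by -1.25 (Ptch1), -1.70 (Gli1), -3.64 (Shh), -2.10 (Hoxd13), -0.42 (Ets2), -0.90 (Sall1), 0.67 (Asb4) and -2.99 (Pitx1). Signalling and mesenchyme genes differed by 1.67 (Wif1), -0.97 (Jag1), -1.68 (Fgf9), 1.16 (Egfr), 0.71 (Prrx2), 1.29 (Tbx18), -0.53 (Ccnd1) and -0.53 (Ccne2). The targeted Hand2 differed by -6.55 and Hand2os1 by 2.25. Genes of chromosome 5 or copies of ribosomal protein genes differed by -9.39 (Rplp0-ps1), 0.48 (Rplp0), 0.82 (Gltp), 0.25 (Dcun1d4) and -1.11 (Rpl34-ps1). The remaining genes differed by -1.47 (Pfkp), -2.01 (Bhlhe40), -2.29 (Bhlhe41), -2.30 (Stc2), 1.64 (Cwc22), 3.72 (Pde7b), 1.27 (Pcdh17), -2.26 (Gja3), -0.76 (Map1b), -0.44 (Olfm1), -0.57 (Cldn6), 1.00 (Kank4), 1.84 (Col6a3), 1.81 (Sned1) and 1.92 (mt-Nd3). Stage, colony, the gene targeted and the kind of loss differ together between both series, so none of them can be told apart as the source of a difference. Depth differs too, but with the Hand2 counts thinned to the Tbx3 depth the test called 277 genes, against 292. This argues against depth as the source of that count, while single genes were not followed.

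All 13 hypoxia and glycolysis genes lay above the wild-type mean in each library labelled Tbx3-deficient, with medians of 0.726, 0.945 and 1.07 on the log2 scale against -0.103, 0.0734 and 0.0355 in the wild types. Scaling is argued against, since 1 factor per library moves all genes alike, while the lower quartile of the list was 0.771 and the upper quartile of all other genes tested 0.122. Embryo sex as the whole cause is argued against by 1 library: deficient replicate 3, female by Xist like the wild types, had the median of 1.07. With the covariate the median was 1.1 (lower quartile 0.948, against 0.771 without). That estimate rests mainly on the same library, as deficient replicates 1 and 2 were male. No member stayed called, since the covariate runs with genotype (correlation -0.737) and widens the errors, as for Pdk1 from 1.52 (SE 0.176) to 1.71 (SE 0.23). Handling before lysis stays open. Its test asked for a clear rise of immediate early genes, and only a clear fall would have counted against it, so unchanged genes could not exclude handling. Those genes had a median of 0.292 (quartiles 0.0938 to 0.385), which met neither. The mitochondrial share of counts was lower without overlap (0.94, 0.78 and 0.83% against 1.06, 1.01 and 1.35% in the wild types), and collection times are not given in the sources used here. A response to the loss of TBX3 or to poorer oxygen supply of these embryos may underlie the rise, and neither was tested.

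Tbx3 counts did not differ between the groups of its own comparison, which goes against a working transcription stop at the start codon unless transcription runs past it (not tested), while genes around it were called more often than elsewhere. A single wrong label as the source of these counts is argued against, since it would leave 2 deficient libraries low and the middle of the 3 was 1.01 times the wild-type mean. For a wrong label of deficient replicate 1, each library was placed between the other group (0) and its own (1), over genes called without it. The lower quartile was at least 0.603 in 5 of the 6 libraries. It was 0.382 in deficient replicate 1 (median 0.57, upper quartile 0.754, 218 genes), which does not decide. Other values argue against a wild-type library under that label. Pitx1 and Rplp0-ps1, called without deficient replicate 1 too, stood there at the level of its group. The 3 copies of Rplp0 summed to 1016 CPM of total counts there. They stood at 1133 and 1045 CPM in deficient replicates 2 and 3 and at 102 to 110.5 CPM in the wild types. All 13 hypoxia and glycolysis genes lay above the wild-type mean in deficient replicate 1. DNA carried along with the targeted allele from another strain is a candidate explanation for the calls near Tbx3 and the copies of Rplp0, with p = 2.93e-05 by Fisher's exact test for calls within 20 Mb (p = 9.39e-05 within 10 Mb and p = 0.164 within 5 Mb), while around Hand2 the same test gave p = 0.915 within 20 Mb and p = 0.0105 within 10 Mb, which leaves it open there. Reads that moved from Rplp0 to its copies may account for the fall of Rplp0, because the log2 ratio was -0.559 for Rplp0 alone and 0.119 for the sum with 3 copies.

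Pitx1, Hoxc6, Hoxc8 and Hoxc9 were called higher in both comparisons, but in the Hand2 comparison Pitx1, Hoxc8 and Hoxc9 lost the call without most single libraries and with the sex covariate (adjusted p of 0.0609, 0.073 and 0.0687). Hindlimb tissue in the Tbx3 series is argued against, as Tbx4 had a log2 fold change of -0.0451 with an upper 95% limit of 0.468, against 4.38 for Pitx1. Body wall tissue stays open: within groups, the mean of 9 body wall markers and the mean of Pitx1, Hoxc6, Hoxc8 and Hoxc9 had a Pearson's r of 0.545 over 12 libraries (p = 0.142) and a Spearman's rho of 0.51 (p = 0.182, both by permutation, 1296 orders), and r was 0.345 without Tbx3 wild-type replicate 1 and Hand2 wild-type replicate 3. Body wall markers had median log2 fold changes of 1.68 in the Tbx3 and 1.12 in the Hand2 comparison. By edgeR 0 of 7 and 1 of 8 were called, and both camera calls were lost with an estimated correlation (adjusted p = 0.534 and 0.58). Their abundant member Gata6 was at 11.4 and 33.4 CPM in the Tbx3 series. There the wild types ran from -0.402 to 1.84 in mean log2 CPM of body wall markers. Their mean of Pitx1 and the Hoxc genes ran only from 2.43 to 2.57. Deficient replicate 3 had 1.63 and 4.24. This argues against body wall as the whole cause in the Tbx3 series, while part of the rise of Pitx1 and the Hoxc genes may still come from it. Loss of a repressor of these genes is the explanation that the groups name, and it was not tested.

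Regrouping the libraries tested each count. In the Tbx3 comparison 1 of 10 splits of the 6 libraries called 153 genes, and the highest other called 6. In the Hand2 comparison 1 of 10 called 1836 genes, and the highest other called 10. For lists the real counts were 14 and 18, and the highest others 11 and 10. With 10 splits a share under 0.05 cannot be reached. For genes called in both, 1 of 100 pairs of splits gave 31, and the highest other gave 1. No other pair could share more than 10 genes, because the other splits called so few, so this adds nothing to the separate counts. For the difference of effects 2 of 60 splits, drawn from 200, called at least 292 genes. The other of these called 568. It kept the real Hand2 groups and mixed the Tbx3 groups, so the Hand2 effect stayed in the contrast and can give many calls by itself. The count therefore cannot show whether both effects differ, and chance in the Tbx3 grouping is not excluded. The 3 draws other than the real one that kept the Hand2 groups called 156, 568 and 56 genes. Among draws that did not keep the Hand2 groups the highest count was 22.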

How the results depend on the processing

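The fits with protein-coding genes only, without genes on the targeted chromosome, on X and Y or like ribosomal RNA, and with thinned counts, and the sex covariate for lists, were chosen after seeing the data. RLE, upper quartile, a filter of 1 CPM in 3 libraries and robust dispersions kept the total counts of genes, and of lists where these were rerun, within 1.5 times, but with upper quartile 504 genes were lower in the Hand2 comparison, against 1018, and the log2 fold changes of Tbx3 and Hand2 kept their side of the threshold in every alternative run for them, which leaves out the 1.5-fold minimum and the fit without the targeted chromosome. Counts that moved further follow, and the cause was not tested unless named. The Tbx3 comparison called 153 genes, but 504 with no filter, 551 with DESeq2, 99 with limma-voom, 87 with the replicate block, 12 with the sex covariate and 422 with all 12 libraries in 1 fit. The Hand2 comparison called 1836 genes, but 3475 with DESeq2, 161 with the replicate block, 550 with the sex covariate and 588 at 1.5-fold or more. It called 1209 with counts thinned from a mean of 65.0 to 26.0 M counts, where fewer reads are the cause by construction. Genes called in both were 31 (27 in the same direction), but 103 (85) with no filter, 186 (152) with DESeq2, 17 (15) with limma-voom, 5 (5) with the replicate block, 0 (0) with the sex covariate, 107 (91) in 1 fit, 14 (12) at 1.5-fold, 47 with protein-coding genes only and 19 (16) without the targeted chromosomes. The difference of effects called 292 genes, but 860 with DESeq2 and 69 with the replicate block. Lists called were 0 and 0 with an estimated correlation (5 and 3 at an unadjusted p under 0.05), and 7 with fry in the Tbx3 comparison. Leaving out single libraries gave 23 to 220 genes (Tbx3), 218 to 2223 (Hand2), 7 to 34 in both, 6 to 32 in the same direction, 123 to 336 for the difference, and 11 to 13 and 10 to 18 lists. The log2 fold change ran from -0.03 to 0.03 for Tbx3 and from -8.70 to -6.57 for Hand2. The replicate numbers do not pair the samples, since same-number libraries correlated at 0.0741, 0.0131 and -0.00797 (Tbx3) and -0.128, 0.031 and 0.0275 (Hand2) after removing group means, so the block uses up degrees of freedom. The red cell list reversed in the Tbx3 comparison with the sex covariate (adjusted p 0.0114). Of 384 list values in the Tbx3 comparison 46 lost and 8 gained the call, and of 429 in the Hand2 comparison 59 and 6. For named genes, 247 of 1781 values lost and 44 gained it in the Tbx3 comparison, and 411 of 2434 and 12 in the Hand2 comparison, 0 with a reversed direction. In simulated data 64% (Tbx3) and 72% (Hand2) of 1.5-fold changes planted in genes of at least 5 CPM were found. Smaller changes, and changes of single genes below 5 CPM, were not simulated.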

Other observations

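The values of Gm8730 and Gm9625 and the test of each were chosen only after the result was seen.

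By Xist and Y-linked counts, 0 of 3 Tbx3 wild-type embryos and 2 of 3 of those labelled Tbx3-deficient were male, as were 1 of 3 Hand2 wild types and 2 of 3 Hand2-deficient embryos. Xist stood at 700 and 182 CPM in the Tbx3 series (log2 fold change -1.94, adjusted p = 0.68).

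The Rplp0 pseudogene Gm8730 was at 1.95 CPM in Hand2 wild-type replicate 2 and 2.30 CPM in Hand2-deficient replicate 3, and at 91.0 to 108 CPM in the other 7 libraries outside the group labelled Tbx3-deficient (CPM of total counts here, without TMM). In the Tbx3 comparison it rose with Gm9625, by 3.15 and 5.48 on the log2 scale. The pseudogene Rpl34-ps1 fell from 170 to 83.2 CPM in the Hand2 comparison (adjusted p = 8.62e-05).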
